A study of Mus musculus with 9 samples.

How the data were processed

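The data were RNA sequencing profiles of induced regulatory T cells from C57BL/6J mice, 4 libraries from Glut1 transgenic and 5 from wild-type mice. Per the labels' protocols, RNA was extracted with RNeasy kits, libraries were made with stranded TruSeq mRNA kits, and 75 bp paired-end reads were sequenced on an Illumina HiSeq instrument. Per the submitters' processing notes, bcl2fastq, TopHat2, featureCounts, DESeq2 and the mouse build mm10 were used; their versions, parameters and strand setting are not given in the sources used here.

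The deposited table of raw counts held whole-number counts per gene for each library, not normalized, for 28111 genes, of which 26416 had a count in any library. The deposited table of log2 values held 13700 genes, those with at least 5 counts in every library. In it the values of WT replicates 1 and 3, the WT libraries of mouse group 1, summed to 0 in each gene. Over 5841 genes with over 500 counts in every library, the columns correlated across genes with log2 of median-ratio normalized counts relative to those libraries at r of at least 0.99996, genes not being independent replicates. How the authors made this log2 table is not stated in the sources used here, and it was used for one alternative only. Its values can be negative, so the intended fits with a pseudocount added to it were not run. Columns were matched to samples by the genotype and number in their names, and genotype, replicate number and mouse group came from the labels.

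Total counts per library were 21679613, 24478463, 24214377, 24152023 and 25390340 in WT replicates 1 to 5 and 26984332, 20881035, 26540733 and 31196428 in Glut1Tg replicates 1 to 4. The 10 genes with the most counts took 5.04% to 6.79% of them. No pair of libraries agreed within sampling noise, so all were kept as separate samples.

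Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr by genotype, which left 14817, and libraries were scaled by TMM. A quasi-likelihood model with mouse group and genotype as terms gave log2 fold changes, SE (the fold change over the square root of F) and p-values, adjusted by the Benjamini-Hochberg method with a threshold of 0.05. CPM were computed on TMM-scaled library totals. The mouse group coefficient and the interaction were tested with the same counts. The median SE of a log2 fold change was 0.25. On simulated counts for 14817 genes with the same design, the genotype test recovered 0.995% of genes changed 1.5-fold, 12.4% of those changed 2-fold and 69.2% of those changed 4-fold, and called 4 of 43731 unchanged genes.

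The 37 gene lists covered T cell lineages, metabolism, growth, signalling, other cell types, RNA quality and sex, and were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, two-sided, adjusted over the lists. List medians and means come from the linear model on log2 CPM, which is the scale of camera, and counts of positive and negative fold changes and single genes come from edgeR. That scale was settled after medians of the edgeR fold changes had been seen. Between these scales the sign of the median differed for 6 lists, none of them called: Th2 (-0.07 against 0.05 in edgeR), Th17 (-0.01 against 0.11), interferon (-0.06 against 0.10), NK cell (-0.17 against 0.86), erythroid and platelet (-0.46 against 0.86) and mast cell and basophil (-0.35 against 0.42). For oxidative phosphorylation the medians were 0.38 and 0.40. In a simulation, 3 of 3 lists of 40 genes changed 1.5-fold and 0 of 60 unchanged lists were called. The simulated genes varied independently. On the real libraries, 100 splits into 4 and 5 were fitted. These were the real one and others drawn at random, out of 125 that could be fitted. Each of the others called from 2 to 18 of the 37 lists with the preset correlation. Exact permutation tests enumerated the 126 splits of 9 libraries into 4 and 5.

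The comparisons, lists, alternatives and rule for naming genes were fixed before the data were examined. The rule named Slc2a1 and Foxp3, then up to 15 genes in each direction with the largest fold changes among named, not predicted, genes that passed, had a mean of at least 1 CPM in the higher genotype and did not overlap between genotypes. Where fewer than 5 passed in a direction it named the 5 with the smallest p. From each list it took up to 4 members that passed or, failing that, had the highest mean CPM, and for mouse group up to 5 genes in each direction with the smallest p. Taking 3 members of called and 2 of other lists was settled after first results had been seen. So was limiting the choices by smallest p, for genotype and mouse group, to protein-coding genes with no predicted symbol and at least 1 CPM, which kept Gm9855 out. Some list members that the rule took are not reported here, and none took their place. Replicate numbers of the labels were not used to pair libraries, as libraries 1, 2 and 4 of the genotypes belonged to different mouse groups.

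The alternatives were other scalings, filters, thresholds and models, DESeq2 1.42.0, limma-voom, single mouse groups, and each library left out in turn. Sex of the mice as a term, males alone, leaving out the libraries apart on the first component, a robust fit, sample weights, a model on the deposited log2 values, exact permutation of list means, lists without Slc2a1, correction for GC content and transcript length (mgcv 1.9.3), a cell cycle covariate and thinning were added after seeing the data. Gene positions, length and GC content came from the GENCODE M21 annotation of the same assembly as mm10, matched by gene identifier for every list member. Reads shared between near-identical copies, overlapping genes or antisense partners cannot be separated in counts per gene. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.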

Results

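Induced regulatory T cells, CD4 T cells that have been driven in culture to express the transcription factor Foxp3, were profiled by mRNA sequencing from C57BL/6J mice. Of the 9 libraries, 4 came from mice carrying a Glut1 transgene (Glut1Tg) and 5 from wild-type controls (WT). Glut1 is a glucose transporter of the plasma membrane encoded by Slc2a1. Each library also carried a mouse group in its labels: mouse group 1 held 3 Glut1Tg and 2 WT libraries, and mouse group 2 held 1 Glut1Tg and 3 WT libraries. What sets the mouse groups apart is not given in the sources used here. Counts per library summed to between 20881035 and 31196428, and 14817 genes were tested. The labels do not say whether the libraries came from separate animals or cultures, so the p-values measure only the spread between these libraries, which may be technical. By sex-linked genes, given below, the Glut1Tg libraries came from both sexes and so not all from a single animal, while all WT libraries came from males.

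On the first principal component of log2 CPM, which held 50.7% of the variance, WT replicate 2 (score 88.2) and Glut1Tg replicate 1 (score 100.5), both of mouse group 2, lay apart from the other 7 libraries. These libraries had the highest values of the proliferation gene Mki67, 1621 and 1652 CPM, against 346 to 808 CPM elsewhere. Il2ra, the alpha chain of the interleukin-2 receptor, stood at 2386 and 2959 CPM in them and at 241 to 690 CPM in the rest. The second component (20.4%) set apart Glut1Tg replicate 3 (score 78.4), in which the mast cell protease Cpa3 reached 1670 CPM and the myeloid gene Lyz2 reached 207 CPM.

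**Figure D1:**
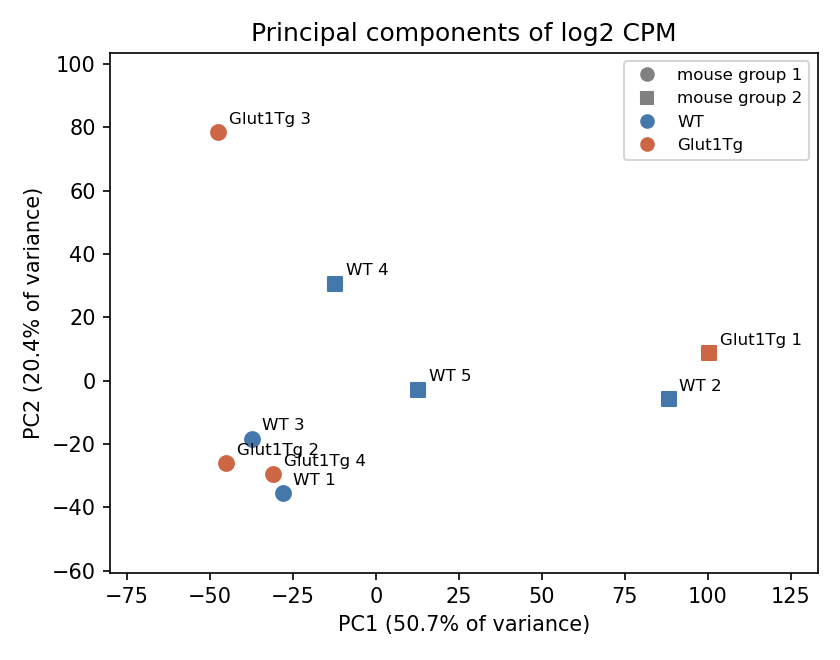
Scores of the 9 libraries on the first (x axis) and second (y axis) principal components of log2 CPM, in arbitrary units, with colour for genotype and symbol shape for mouse group. WT replicate 2 and Glut1Tg replicate 1 lie at 88.2 and 100.5 on the first component, and Glut1Tg replicate 3 lies at 78.4 on the second.

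Slc2a1, the gene of the transgene's product, was examined first because it checks the genotype labels. Its transcripts stood at 373 ± 121 CPM in Glut1Tg (SD, n = 4) and 42.1 ± 12.6 CPM in WT (SD, n = 5). The individual values were 260.2, 496, 279 and 457 CPM in Glut1Tg replicates 1 to 4, and 52.0, 36.6, 58.7, 33.3 and 29.7 CPM in WT replicates 1 to 5, so all 4 transgenic libraries lay above all 5 controls. With mouse group in the model, Slc2a1 rose 7.58-fold (95% interval 5.65 to 10.2; log2 fold change 2.92, SE 0.19; edgeR adjusted p = 0.000903; exact two-sided permutation p = 0.00794, the smallest that 126 splits can give). The gene, ENSMUSG00000028645, lies on the plus strand of chromosome 4 from 119108711 to 119137983 in mm10, and counts per gene do not separate transcripts of the transgene from those of the endogenous copy. Without Glut1Tg replicate 1 the fold change was nearly as large (log2 2.89) but the edgeR adjusted p was 0.0518.

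Foxp3, the lineage-defining factor of regulatory T cells, had 747 ± 93.3 CPM in Glut1Tg (SD, n = 4) and 977 ± 135 CPM in WT (SD, n = 5). The fitted fold was 0.821 (95% interval 0.664 to 1.01; log2 fold change -0.28, SE 0.14), which did not pass the test across genes (edgeR adjusted p = 0.681). For this gene alone, without the mouse group term, the exact two-sided permutation p was 0.0238. The gene (ENSMUSG00000039521) lies on the plus strand of chromosome X from 7573644 to 7595245.

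**Figure D2:**
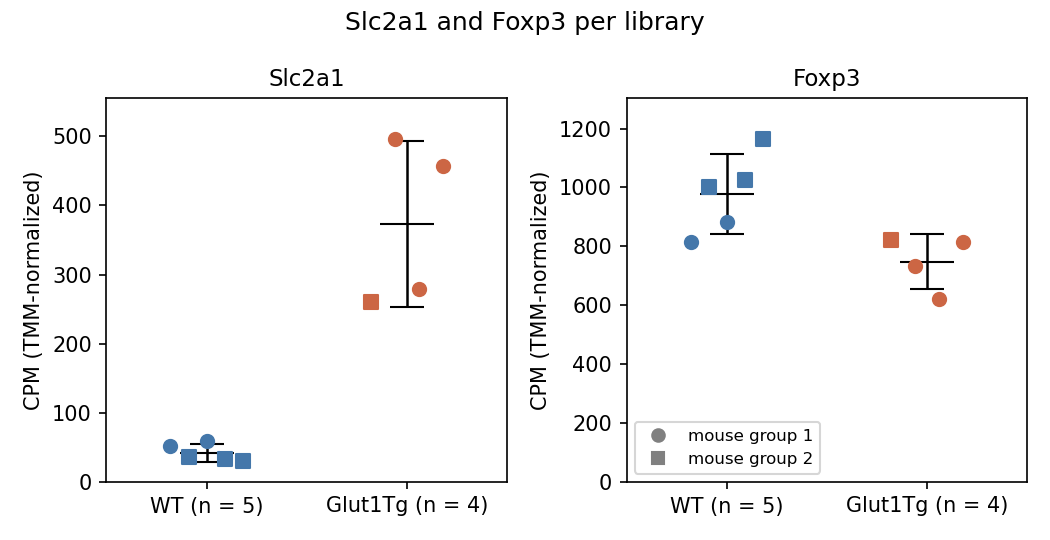
Slc2a1 and Foxp3 in each library as TMM-normalized CPM (y axis, from 0) for WT and Glut1Tg (x axis), with circles for mouse group 1 and squares for mouse group 2; long ticks and bars give the mean and SD of the 5 WT and 4 Glut1Tg libraries. Slc2a1 lies between 260.2 and 496 CPM in Glut1Tg and between 29.7 and 58.7 CPM in WT, while the Foxp3 values of the genotypes overlap.

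Across the transcriptome, Slc2a1 was the single gene that differed between Glut1Tg and WT (1 higher and 0 lower by edgeR's quasi-likelihood test, adjusted p under 0.05). The next smallest adjusted p was 0.681. At an unadjusted p under 0.05 there were 889 genes, 667 higher and 222 lower in Glut1Tg, where 741 would be expected by chance. The genotypes did not overlap in 236 genes (1.59%, against 1.59% by chance). The count was 0 without Glut1Tg replicate 1, 2 without Glut1Tg replicate 2 and 0 without both libraries apart on the first component. DESeq2 called 7 genes and limma-voom called 1, with 1144 and 894 genes at an unadjusted p under 0.05. The median gene had a 95% half-width of 1.48-fold around its fold change. In counts simulated with this design, 12.4% of genes changed 2-fold and 69.2% of genes changed 4-fold were recovered, so most changes of 2-fold or less in a single gene were not detectable.

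The genes with the smallest p after Slc2a1 are given as values that did not pass (edgeR adjusted p = 0.681 for each). In the direction of higher in Glut1Tg these were Reep3, a gene of the endoplasmic reticulum (167 ± 42.5 CPM against 76.3 ± 20.8), the sialyltransferase gene St6galnac4 (53.2 ± 9.71 against 34.3 ± 4.67), and the replication-dependent histone genes Hist1h3f (1.49 ± 1.26 against 0.552 ± 0.286) and Hist1h3e (1.65 ± 0.902 against 0.694 ± 0.343). The histone genes have near-identical copies among which reads could be split. In the other direction were the inhibitory receptor gene Cd200r1 (3.41 ± 3.08 against 12.3 ± 7.47 CPM), the cyclic nucleotide-gated channel gene Cnga1 (0.922 ± 0.295 against 2.88 ± 1.45), the Notch target Hey1 (0.566 ± 0.222 against 1.38 ± 0.728), the interferon-inducible GTPase gene Gbp9 (50.8 ± 25.9 against 84.4 ± 60.9) and the cholesterol exporter gene Abca1 (12.7 ± 6.81 against 23.7 ± 9.54). All are means ± SD of 4 Glut1Tg and 5 WT libraries and take no account of mouse group, unlike the test. Cd200r1 stood at 2.82 CPM in mouse group 1 and 15.3 in mouse group 2, and its fold fitted with mouse group was 0.448. Gbp9 stood at 97.6 and 34.4 CPM in mouse groups 1 and 2, and its fitted fold was 0.371. Without the mouse group term the exact two-sided permutation p of Gbp9 was 0.508. DESeq2 called Reep3, Cd200r1, Cnga1, Gbp9 and Hey1 besides Slc2a1 and the predicted gene Gm9855, the last named after its values were seen.

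Gene lists fixed beforehand were tested next. Of 37 lists, camera with a preset correlation between genes called 15, of which 12 were higher and 3 lower in Glut1Tg. None was called with an estimated correlation (lowest adjusted p = 0.689 with an estimated correlation), by fry for direction (lowest adjusted p = 0.127), or by exact permutation of list means (lowest adjusted p = 0.294). The exact permutation left out mouse group. The sex-linked list reached its smallest possible p, 0.00794, and even this became 0.294 after adjustment. A single list could thus not pass by exact permutation, and the lack of calls there shows little. Slc2a1 was the single list member that passed the edgeR test, over all genes and adjusted over the list alone. In the lists without Slc2a1, 0 members passed over all genes and 0 passed adjusted over the list alone. Glut1Tg replicates 1 and 3, which stood apart on the first and second components, held the highest means of the Glut1Tg libraries in the higher lists. The exception was the ribosomal proteins, where replicate 1 was lowest (-0.16 relative to the WT mean, against 0.79 in replicate 3). In the cell cycle list replicate 1 lay above the WT mean (1.54) and replicate 3 below it (-0.18). WT replicate 2 lay high as well in several of these lists, such as the cell cycle (1.38) and fatty acid and cholesterol synthesis (0.88). Without Glut1Tg replicate 1 camera called 7 lists, and of the 15 the called ones were oxidative phosphorylation, MYC targets, ribosomal proteins, the pentose phosphate pathway and sex-linked genes. The interferon (adjusted p = 0.00137) and myeloid (adjusted p = 0.0277) lists were added as higher. In these, Glut1Tg replicate 3 stood at 1.13 and 2.89 relative to the WT mean. Replicate 2 stood at -0.36 and 0.18 and replicate 4 at -0.12 and -0.21, so 1 library was high in both lists. Without Glut1Tg replicate 3 camera called 16, with the interferon (adjusted p = 0.000952) and erythroid and platelet (adjusted p = 0.0198) lists added as lower. With no mouse group term camera called 8, and cell cycle, glycolysis, the pentose phosphate pathway, the tricarboxylic acid cycle, fatty acid and cholesterol synthesis, Th1 and naive and central memory genes lost the call.

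The list with the smallest camera p was that of nuclear-encoded oxidative phosphorylation genes, the subunits of the respiratory chain and ATP synthase. Of its 70 measured members, 69 had a positive fold change and 29 were higher at an unadjusted p under 0.05. The median log2 fold change was 0.38 (camera adjusted p = 8.67e-18 with the preset correlation; adjusted p = 0.689 with an estimated correlation). Relative to the WT mean, the list mean stood at 0.43, 0.09, 0.73 and 0.09 on the log2 scale in Glut1Tg replicates 1 to 4, and between -0.14 and 0.20 in WT. Atp5a1 had 846 ± 72.6 CPM in Glut1Tg and 730 ± 78.8 in WT, Atp5b 812 ± 396 and 667 ± 233, and Cox4i1 424 ± 124 and 328 ± 39.98 (SD, n = 4 and n = 5). The 13 mitochondrially encoded genes were not called (camera adjusted p = 0.932). In that list mt-Co1 had 9043 ± 1843 CPM in Glut1Tg and 9273 ± 1853 in WT, and mt-Cytb had 4105 ± 949 and 3734 ± 687.

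Growth lists also stood higher. All 28 measured MYC targets and ribosome biogenesis genes had positive fold changes, 15 of them at an unadjusted p under 0.05, with a median log2 fold change of 0.62 (camera adjusted p = 7.06e-12; adjusted p = 0.689 with an estimated correlation). The list means were 1.05, 0.05, 0.83 and 0.04 above the WT mean in Glut1Tg replicates 1 to 4, and without replicate 1 the median was 0.28 (camera adjusted p = 0.000531). Nucleolin (Ncl) had 1031 ± 178 CPM against 808 ± 125 in WT, nucleophosmin (Npm1) 1011 ± 232 against 781 ± 108, and the polyamine enzyme gene Odc1 419 ± 91.2 against 323 ± 96.4. Cytosolic ribosomal protein genes had positive fold changes in 59 of 60, 1 at an unadjusted p under 0.05 (median 0.19; camera adjusted p = 8.97e-06; adjusted p = 0.739 with an estimated correlation), among them Rplp0 at 3547 ± 479 against 2927 ± 189 CPM, Rpl4 at 3356 ± 651 against 2766 ± 226 and Rps9 at 2498 ± 646 against 1980 ± 297. The median of that list was 0.36 without Glut1Tg replicate 1, 0.07 without Glut1Tg replicate 3 0.10 without WT replicate 3 and 0.30 with no mouse group term, and it was called each time. All 37 cell cycle genes had positive fold changes, 0 at an unadjusted p under 0.05 (median 0.47; camera adjusted p = 1.88e-05; adjusted p = 0.724 with an estimated correlation). Their means did not separate the genotypes without the mouse group term, as Mki67 stood at 775 ± 594 against 773 ± 498 CPM, Top2a at 598 ± 643 against 680.0 ± 623 and Mcm6 at 296 ± 222 against 267 ± 153. The cell cycle list was not called with no mouse group term (median 0.04; camera adjusted p = 0.944) or without Glut1Tg replicate 1 (median 0.03; camera adjusted p = 0.740). Genes of endoplasmic reticulum stress were positive in 17 of 23, 5 at an unadjusted p under 0.05 (median 0.36; camera adjusted p = 0.0188; adjusted p = 0.696 with an estimated correlation), with the chaperone genes Pdia3 at 707 ± 119 against 638 ± 80.7 CPM, Calr at 666 ± 151 against 512 ± 115 and Hspa5 at 598 ± 113 against 443 ± 103, and were not called without Glut1Tg replicate 1 (median 0.10; camera adjusted p = 0.467). With no mouse group term they were called, with a median of 0.14.

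Lists of carbon metabolism were called in the same direction with the preset correlation. Relative to the WT mean, with no mouse group term, glycolysis means were 0.77, -0.07, 0.42 and -0.16 in Glut1Tg replicates 1 to 4. They stood at 0.49 in WT replicate 2. For fatty acid and cholesterol synthesis they were 1.11, -0.36, 0.29 and -0.29, with 0.88 in WT replicate 2. Glut1Tg replicates 2 and 4 also lay below the WT mean for the pentose phosphate pathway, the tricarboxylic acid cycle and Atf4 targets. Glycolysis was positive in 21 of 26 genes, 4 at an unadjusted p under 0.05 (median 0.40; camera adjusted p = 0.00166; adjusted p = 0.689 with an estimated correlation). Pkm stood at 1090 ± 530 CPM in Glut1Tg and 840 ± 309 in WT, Ldha at 895 ± 555 and 677 ± 297, and Eno1 at 708 ± 484 and 481 ± 292. The pentose phosphate pathway was positive in 10 of 11, 3 at an unadjusted p under 0.05 (median 0.32; camera adjusted p = 0.00166; adjusted p = 0.689 with an estimated correlation). Tkt stood at 355 ± 137 and 270 ± 72.0, Taldo1 at 188 ± 63.8 and 151 ± 22.9, and Pgd at 95.9 ± 28.4 and 80.4 ± 13.7 CPM. The tricarboxylic acid cycle was positive in 28 of 30, 3 at an unadjusted p under 0.05 (median 0.19; camera adjusted p = 0.000783; adjusted p = 0.689 with an estimated correlation). Mdh2 stood at 269 ± 80.3 and 224 ± 44.8, and Sdha at 234 ± 66.1 and 244 ± 49.8 CPM (log2 fold change of Sdha fitted with mouse group 0.14). Fatty acid and cholesterol synthesis was positive in 27 of 30, 0 at an unadjusted p under 0.05 (median 0.46; camera adjusted p = 2.96e-05; adjusted p = 0.696 with an estimated correlation). Srebf2 stood at 320 ± 89.5 and 278 ± 49.9, Acly at 208 ± 58.6 and 219 ± 44.3 (log2 fold change fitted with mouse group 0.06), and Scd2 at 238 ± 23.7 and 195 ± 45.5 CPM. Amino acid transport and synthesis genes, targets of Atf4, were positive in 25 of 27, 1 at an unadjusted p under 0.05 (median 0.35; camera adjusted p = 0.000861; adjusted p = 0.696 with an estimated correlation). Slc1a5 stood at 219 ± 67.9 and 220 ± 30.8, Atf4 at 258 ± 105 and 187 ± 32.03, and Slc38a2 at 199 ± 17.5 and 216 ± 44.8 CPM. Hypoxia and HIF-1 targets were positive in 19 of 25, with 2 higher and 1 lower at an unadjusted p under 0.05 (median 0.23; camera adjusted p = 0.0427; adjusted p = 0.689 with an estimated correlation). Hif1a itself stood at 239 ± 62.6 and 212 ± 88.6 CPM. Slc2a1 belongs to this list, and without it the call was lost (camera adjusted p = 0.224). It was also lost without WT replicate 1 (0.0739), WT replicate 5 (0.0553), Glut1Tg replicate 1 (0.141, median 0.14), Glut1Tg replicate 2 (0.0865) or Glut1Tg replicate 3 (0.153, median 0.13). Without Glut1Tg replicate 4 it was kept, with a median of 0.35. Without Glut1Tg replicate 1 the median was 0.23 for glycolysis (camera adjusted p = 0.141), 0.11 for the tricarboxylic acid cycle (0.0607), 0.15 for fatty acid and cholesterol synthesis (0.216) and 0.16 for the Atf4 targets (0.428), none of which passed. With no mouse group term 4 of these lists were not called: glycolysis (median 0.25; camera adjusted p = 0.0932), the pentose phosphate pathway (median 0.17; 0.265), the tricarboxylic acid cycle (median 0.08; 0.173) and fatty acid and cholesterol synthesis (median 0.18; 0.173).

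The remaining metabolic lists were not called by camera. Glucose transporters (6 measured; camera adjusted p = 0.511) and hypoxia targets were the 2 lists that fry called for change in either direction, and both hold Slc2a1. The second transporter by mean level over all libraries, Slc2a6, had 56.6 ± 4.62 CPM in Glut1Tg and 47.5 ± 13.1 in WT. In WT its mean lay above the 42.1 ± 12.6 CPM of Slc2a1. Fatty acid oxidation (camera adjusted p = 0.224) included Hadha at 148 ± 29.7 and 155 ± 22.6 CPM and the entry enzyme gene Cpt1a at 121 ± 60.7 and 160.2 ± 54.5. Glutamine metabolism (camera adjusted p = 0.213) included Glud1 at 386 ± 27.0 and 381 ± 39.8. The mTOR and AKT pathway (camera adjusted p = 0.932) included the kinase genes Pik3cd at 770 ± 166 and 723 ± 114 and Pik3r1 at 317 ± 123 and 316 ± 124. Apoptosis and p53 targets (camera adjusted p = 0.535) included Trp53inp1 at 603 ± 351 and 575 ± 373 and Mcl1 at 615 ± 186 and 561 ± 89.7, and autophagy and lysosome genes (camera adjusted p = 0.232) included Sqstm1 at 471 ± 218 and 391 ± 197 and Ctsd at 388 ± 138 and 325 ± 81.0.

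Among lineage lists, Th1 genes were positive in 16 of 18, 3 at an unadjusted p under 0.05 (median log2 fold change 0.46; camera adjusted p = 0.00997; adjusted p = 0.689 with an estimated correlation). Runx3 had 135 ± 35.1 CPM in Glut1Tg and 130.3 ± 26.4 in WT, and Il18r1 had 84.7 ± 42.6 and 130.4 ± 38.6. Tfh genes were negative in 8 of 10, 1 at an unadjusted p under 0.05 (median -0.51; camera adjusted p = 0.0109; adjusted p = 0.689 with an estimated correlation). Il6st stood at 262 ± 149 and 284 ± 77.7, Slamf6 at 71.0 ± 16.0 and 120 ± 40.7 and Bcl6 at 62.3 ± 58.1 and 60.9 ± 54.5 CPM. The Bcl6 mean was slightly higher in Glut1Tg, while its log2 fold change fitted with mouse group was -0.56. Naive and central memory genes were negative in 14 of 18, 1 at an unadjusted p under 0.05 (median -0.45; camera adjusted p = 0.00732; adjusted p = 0.696 with an estimated correlation). Ccr7 stood at 1258 ± 926 and 1084 ± 707, Tcf7 at 1005 ± 653 and 973 ± 328, and S1pr1 at 951 ± 686 and 873 ± 479 CPM. These 3 means were higher in Glut1Tg, while the fold changes fitted with mouse group were -0.35, -0.49 and -0.65. The means of the naive and central memory list in Glut1Tg replicates 1 to 4 were -0.84, 0.36, -0.38 and 0.30 relative to the WT mean. Without Glut1Tg replicate 1 none of these 3 lists was called: the medians were 0.18 for Th1 (camera adjusted p = 0.141), -0.30 for Tfh (0.0607) and -0.22 for naive and central memory genes (0.668). Without Glut1Tg replicate 3 all 3 were called, with medians of 0.27 for Th1 and -0.25 for naive and central memory genes, and without Glut1Tg replicate 4 the Th1 median was 0.70. With no mouse group term Th1 (median 0.31; camera adjusted p = 0.265) and naive and central memory genes (median -0.13; 0.220) were not called, and Tfh genes were, with a median of -0.31.

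The regulatory T cell signature was not called (20 of 31 positive; median 0.15; camera adjusted p = 0.368), nor were Th2 (camera adjusted p = 0.661), Th17 (0.539), chemokine and homing receptor (0.224), inhibitory receptor (0.518), immediate early (0.932), Toll-like receptor and NF-kB (0.518), interferon (0.895) and cytotoxic (0.780) genes, each value being a camera adjusted p. Il2ra of the signature list had 980.5 ± 1320 CPM in Glut1Tg and 837 ± 878 in WT. Il4ra had 313 ± 104 and 242 ± 24.1, Stat6 212 ± 73.5 and 274 ± 44.3, Stat3 479 ± 76.1 and 462 ± 57.5, and Rora 68.9 ± 39.6 and 81.9 ± 67.1. Ctla4 had 483 ± 134 and 485 ± 160, Cd274 110.1 ± 58.5 and 71.6 ± 31.9, Nfkbia 677 ± 259 and 783 ± 255, Tnfaip3 411 ± 295 and 486 ± 265, and Nfkb1 471 ± 179 and 469 ± 113. Igtp had 573 ± 164 and 523 ± 186, Ctsw 690 ± 180 and 643 ± 45.0, and Lamp1 270 ± 72.6 and 225 ± 49.1. For the immediate early, mTOR, cytotoxic and mitochondrially encoded lists the sign of the median, the mean and the camera direction differed.

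**Figure D3:**
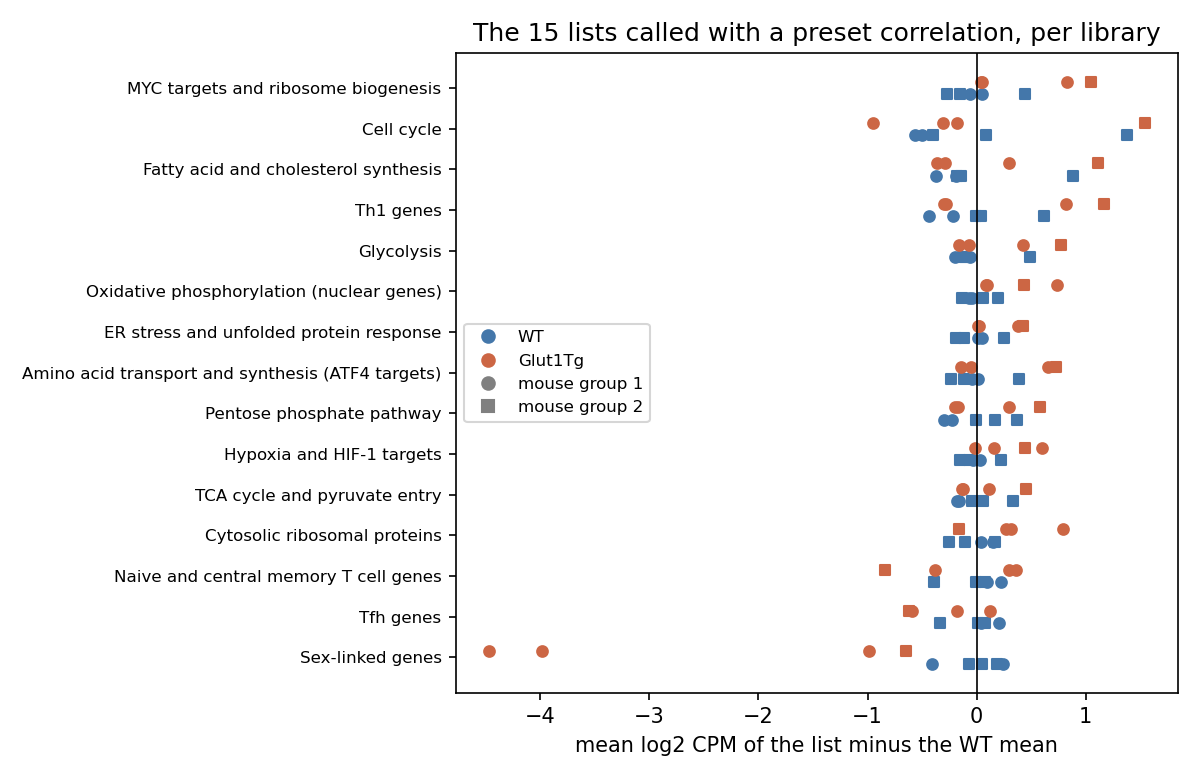
Mean log2 CPM of each of the 15 lists called with the preset correlation, relative to the WT mean (x axis, log2 units), 1 row per list, with a point for each of the 9 libraries coloured by genotype and shaped by mouse group. In the oxidative phosphorylation row Glut1Tg replicates 1 and 3 lie at 0.43 and 0.73, and replicates 2 and 4 lie at 0.09.

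Markers of other cell types were measured alongside. Mast cell and basophil genes varied over the libraries, with Cpa3 at 151, 2.48, 286, 524 and 91.3 CPM in WT replicates 1 to 5 and at 3.56, 364, 1670 and 116 CPM in Glut1Tg replicates 1 to 4. Between genotypes no call was made for this list (camera adjusted p = 0.745), for myeloid and dendritic (0.743), erythroid and platelet (0.661), B cell (0.932), CD8 T cell (0.661) or NK cell (0.877) markers. Glut1Tg replicate 3 held the highest list mean of the 9 libraries in the mast cell, myeloid, erythroid and platelet, B cell and NK cell lists. Its levels were 507 CPM of the platelet factor gene Pf4, 438 CPM of Itga2b, 217 CPM of Cd74 and 110.0 CPM of Fcer1g, with at most 94.8, 156, 132 and 21.6 CPM elsewhere. Kit had 109 ± 16.0 CPM in Glut1Tg and 112 ± 25.0 in WT, Ctss 325 ± 83.3 and 335 ± 69.6, Ighm 549 ± 186 and 559 ± 206, Cd8b1 7.77 ± 0.957 and 8.22 ± 0.406, and Eomes 12.4 ± 11.2 and 6.10 ± 0.978. Sex-linked genes were called lower (4 of 5 negative; camera adjusted p = 0.0272; adjusted p = 0.689 with an estimated correlation). The call was lost without WT replicate 1 (0.108), WT replicate 2 (0.0518), WT replicate 3 (0.0743), Glut1Tg replicate 2 (0.0924) or Glut1Tg replicate 4 (0.0762). Xist, expressed from the inactive X of females, stood at 256 and 340.2 CPM in Glut1Tg replicates 2 and 4 and at up to 1.32 CPM in the other 7 libraries. Conversely the Y-linked genes Ddx3y and Eif2s3y stood at up to 0.298 CPM in these 2 libraries, and at 57.5 CPM or more in the others, so all 5 WT and 2 Glut1Tg libraries came from males.

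**Figure D4:**
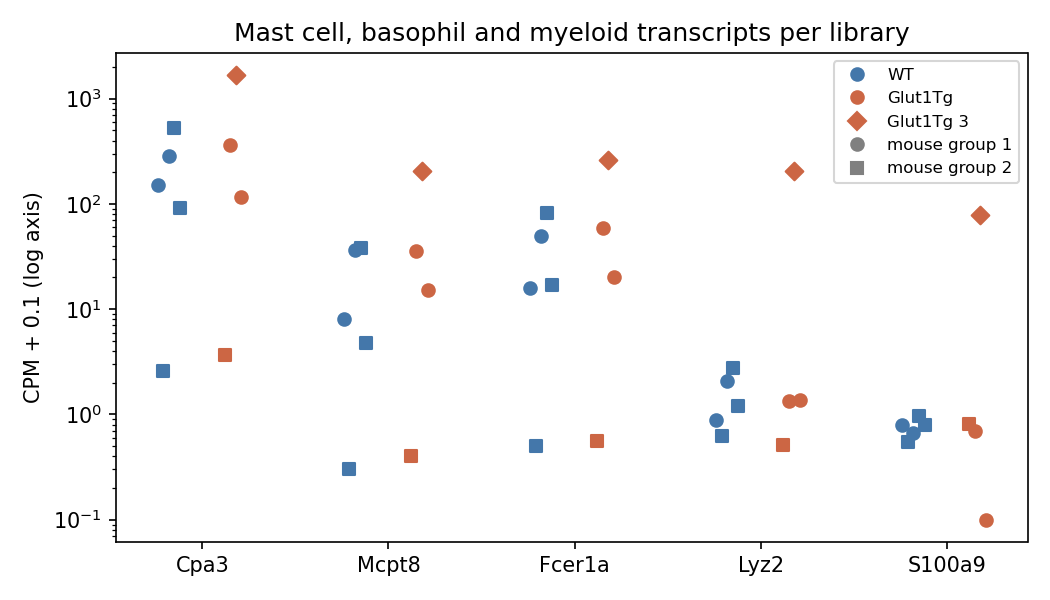
CPM + 0.1 (y axis, log scale) of the mast cell and basophil genes Cpa3, Mcpt8 and Fcer1a and the myeloid genes Lyz2 and S100a9 (x axis) in each of the 9 libraries, coloured by genotype, with circles for mouse group 1, squares for mouse group 2 and a diamond for Glut1Tg replicate 3. That library has the highest value of each gene, such as 207 CPM of Lyz2.

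Mouse group, entered as a covariate above, was itself compared to show how much it could bear on the genotypes. Genes with raised levels in mouse group 2 included those of the DNA-binding protein Pura (75.9 ± 8.09 CPM, n = 4, against 24.0 ± 1.23, n = 5), the menin gene Men1 (54.3 ± 3.42 against 17.8 ± 2.21), Obfc1 (43.2 ± 2.80 against 16.1 ± 1.27), Irf2bp1 (44.0 ± 4.56 against 14.3 ± 2.10) and the transcription factor gene Nfe2l1 (94.2 ± 17.97 against 34.9 ± 2.68). Lower there were Arid5a, an RNA-binding regulator (126 ± 6.07 against 463 ± 49.9), the MYC antagonist Mnt (49.4 ± 2.38 against 149.8 ± 16.4), the NF-kB subunit Relb (66.5 ± 4.25 against 211 ± 26.2), Crtam (1.34 ± 0.488 against 16.3 ± 2.90) and the splicing factor gene Rbm39 (395 ± 47.1 against 1051 ± 73.4). Each of these 10 passed with an edgeR adjusted p of 0.00105 or 0.0012. In all, 3576 genes (24.1%) differed, 1946 higher and 1630 lower in mouse group 2. Of 37 cell cycle genes 28 rose and 0 fell in mouse group 2, and of 25 autophagy and lysosome genes 1 rose and 11 fell. The cell cycle list mean was highest in WT replicate 2 (1.38 relative to the WT mean) and Glut1Tg replicate 1 (1.54), while WT replicates 4 (-0.40) and 5 (0.08), also of mouse group 2, lay nearer to the -0.95 to -0.18 of mouse group 1.

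By camera with the preset correlation 9 lists differed between the mouse groups, and none did with an estimated correlation (lowest adjusted p = 0.8287 with an estimated correlation). Cell cycle, fatty acid and cholesterol synthesis, fatty acid oxidation, the tricarboxylic acid cycle, the pentose phosphate pathway and Th1 genes were higher in mouse group 2, and ribosomal proteins, autophagy and lysosome genes and mast cell and basophil markers were lower. Without WT replicate 2 and Glut1Tg replicate 1, the libraries apart on the first component, camera called 4 lists: cell cycle (adjusted p = 0.0250), the pentose phosphate pathway (0.0466), autophagy and lysosome genes (0.0142) and, not called before, mitochondrially encoded genes (0.0463). The others were not called, with adjusted p = 0.801 for fatty acid and cholesterol synthesis, 0.649 for ribosomal proteins, 0.175 for the tricarboxylic acid cycle and Th1 genes, 0.0658 for fatty acid oxidation and 0.968 for mast cell markers. Mast cell list means were -3.65 in WT replicate 2 and -3.19 in Glut1Tg replicate 1, against 2.01 in WT replicate 4 and -0.04 in WT replicate 5. Without WT replicate 2 and Glut1Tg replicate 1 the mouse groups differed in 678 genes, and with 1 library left out in 681 (Glut1Tg replicate 1), 1909 (WT replicate 1), 1966 (WT replicate 3) and 2148 (WT replicate 2). Among WT libraries alone 623 genes differed.

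Whether the effect of the transgene depended on mouse group was tested with an interaction term. No gene passed (0 of 14817 by edgeR, lowest adjusted p = 0.741; 786 at an unadjusted p under 0.05, against 741 by chance). DESeq2 called 2 genes, Aldh1l1 and Gm8730, named after their values were seen, with 1128 at an unadjusted p under 0.05. Mouse group 2 held 1 Glut1Tg library, which limits what this test can show.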

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

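The tests of depth, of the libraries that stand apart and of the cell cycle were chosen after the data and the 3576 genes had been seen, but before their own results, and so were the limits that decide each of them and the splits.

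In 30 of 272 groups of libraries (named genes, lists and total counts, each within a genotype) 1 library lay far from the others by Dixon's ratio, its gap to the nearest library over the whole range, where chance gives about 1 in 20 groups, or 14. The genes named for mouse group are among them, and Glut1Tg replicate 1, the one Glut1Tg library of mouse group 2, lies apart in these by that choice. Without them it was 23 of 252 groups, against about 13 by chance. Glut1Tg replicate 1 was the library in 8 of the 23, and the ratio took no account of mouse group. Of its items, Gbp9, Sdha, Hist1h3f and Mcm6 also differed between mouse groups (edgeR adjusted p from 0.00395 to 0.0238). So did its fatty acid oxidation and autophagy lists (camera, preset correlation), while Ighm and Ctss did not. The excess over chance thus still holds mouse group differences. The ratio is printed after each name. Glut1Tg replicate 1 was the library in 15 cases. It was highest for Hist1h3f (0.858), Sdha (0.944), Mcm6 (0.856), Pura (0.982), Men1 (0.872), Obfc1 (0.841), Nfe2l1 (0.88) and the fatty acid oxidation list (0.865). It was lowest for Gbp9 (0.958), Ighm (0.857), Crtam (0.84), Ctss (0.905), Arid5a (0.965), Rbm39 (0.963) and the autophagy and lysosome list (0.843). WT replicate 2 was the library in 8 cases: highest for Pkm (0.813), Atp5b (0.812), Mcm6 (0.754) and the regulatory T cell signature (0.73), glycolysis (0.799) and fatty acid and cholesterol synthesis (0.817) lists, and lowest for Nfkbia (0.751) and Tnfaip3 (0.745). Glut1Tg replicate 3 was highest for Atf4 (0.884), Hspa5 (0.933) and Lyz2 (0.834) and lowest for Glud1 (0.869). Glut1Tg replicate 4 was lowest for Scd2 (0.886), WT replicate 3 for Slc1a5 (0.845) and WT replicate 5 for the mitochondrially encoded list (0.733).

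The 3576 genes that differed between mouse groups were set against 4 explanations. Of 100 splits of the libraries into 4 and 5, the real one included, 1 gave as many genes. The highest other split gave 1 gene. This argues against chance, though 1 in 100 is the smallest share that these splits could give. The other splits left the mouse group difference in the spread between libraries, which can lower their counts. With every library thinned to the smallest total, 95.89% of the genes stayed called with the same sign, which argues against depth. Without the libraries apart on the first component 16.08% stayed called, and with the cell cycle mean in the model 15.21% did; 99.69% and 96.2% kept their sign, which the libraries shared between the fits favour. How much either may have contributed cannot be told apart from the smaller number of libraries and from the overlap of proliferation with mouse group, and what the mouse groups are stays open.

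The number of genes that differed between Glut1Tg and WT, 1, was reached by 5 of 100 splits, the real one included, so for the count by itself chance cannot be excluded. The highest other split gave 885 genes. It set WT replicates 1 and 3 and Glut1Tg replicates 2 and 4 against the rest, which with mouse group in the model compares Glut1Tg replicate 3 alone with the other 4 libraries of mouse group 1, so its genes are those of 1 library. Of the 100 splits, 4 compare 1 library in this way, and among the other 96, counted after this was seen, 3 gave as many genes and 16 as many lists. For the lists, 17 of 100 splits gave at least the 15 of the real split, with 18 as the highest other, so chance cannot be excluded there either.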

How the results depend on the processing

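Slc2a1 kept its direction in 25 alternatives, with log2 fold changes of 2.69 to 3.15, and passed the threshold in 20 (adjusted p from 9.5e-41 to 1). It was 3.03 with the replicate block (adjusted p = 1), 2.89 in mouse group 1 alone (0.489), 2.97 in mouse group 2 alone (0.425) and 2.89 without the libraries that stand apart (0.0919), fits with fewer libraries, and none of these passed. Leaving out 1 library in turn gave 2.84 to 3.05, and it did not pass without Glut1Tg replicate 1 (0.0518). In mouse group 2 alone the lone Glut1Tg library was assumed to vary like the others. The count of genes differing between genotypes was 0 with the replicate block, in mouse group 1 alone, in mouse group 2 alone and without the libraries that stand apart, 2 with no filter (Slc2a1 and Gbp6), 7 with DESeq2 and 11 with sample weights (the Y-linked Kdm5d, Ddx3y and Eif2s3y among them); the cause was not tested. With 1 library left out it ran from 0 (without Glut1Tg replicate 1) to 2 (without Glut1Tg replicate 2, adding Gm9855).

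Of the lists, oxidative phosphorylation and MYC targets stayed called in the same direction in all 22 alternatives that kept the preset correlation. The count of called lists was 8 with no mouse group term and 7 with the replicate block, where ER stress (adjusted p = 0.0730) and the 7 lists lost with no mouse group term were not called. It was 9 in mouse group 1 alone, 10 without the libraries that stand apart, 0 with an estimated correlation, 0 by fry for direction and 2 by fry for either direction. Exact permutation gave 0, but it could not call a single list by itself. With 1 library left out the count of called lists ran from 7 (without Glut1Tg replicate 1) to 16. Glut1Tg replicate 3 had the highest interferon list mean of all libraries, 1.13 relative to the WT mean. The median of the interferon list was -0.06 in all libraries. It ran from -0.3202 (without Glut1Tg replicate 3) to 0.311 (without Glut1Tg replicate 1) with 1 library left out. Against the direction in all libraries, it was also 0.311 in mouse group 1 alone and 0.3111 without the libraries that stand apart, that of the mast cell list was 1.268 in mouse group 1 alone and 1.268 without the libraries that stand apart, and that of ribosomal proteins -0.1126 in mouse group 2 alone; the cause was not tested.

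Genes differing between mouse groups numbered 623 in WT alone, 678 without the libraries that stand apart, 665 with the cell cycle mean and 681 (without Glut1Tg replicate 1) to 4518 (without Glut1Tg replicate 3) with 1 library left out; they numbered 1909, 2148 and 1966 without WT replicates 1, 2 and 3. The 10 genes named for mouse group passed in each of 16 alternatives. DESeq2 called 2 genes for the interaction. Of 97 other named genes, 52 had a genotype fold of the other sign in at least 1 of 25 alternatives and 7 were called in at least 1; of 22 lists not called, 19 had a median of the other sign in at least 1 of 22 alternatives. A fit of the deposited log2 values with a pseudocount was not run, as they can be negative. Replicate numbers did not pair the libraries: same-numbered deviations correlated at -0.512, -0.592, 0.226 and -0.212. The sex, male, separate-library, robust, weighted, deposited log2, permutation, GC, cell cycle and thinning alternatives were chosen after seeing the data, the genotype count of 0 without the libraries that stand apart having been seen first.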

Other observations

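The tests of the mast cell and myeloid transcripts, the histone and ribosomal RNA comparisons and the count limits for genes read in some libraries alone were chosen after the values were seen, and the GC content and male tests of oxidative phosphorylation after its call but before their own results.

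Replication-dependent histone transcripts, most of which lack a poly(A) tail, were grouped after the histone genes Hist1h3f and Hist1h3e had come up among the smallest p-values. Their summed level was 131 ± 10.8 CPM in Glut1Tg (SD, n = 4) and 97.0 ± 5.91 CPM in WT (SD, n = 5; exact two-sided permutation p = 0.00794, the smallest that the 126 splits can give), with 144.9, 120.7, 134.4 and 124.8 in Glut1Tg replicates 1 to 4 and 102.9, 94.66, 89.66, 103.3 and 94.39 in WT replicates 1 to 5. Of 39 such genes tested 35 had a positive fold change and 25 were higher at an unadjusted p under 0.05, with 0 lower and 0 passing adjustment (edgeR, lowest adjusted p = 0.681). The genes that prompted the grouping came from this same comparison and belong to the group, so these p-values are not an independent test of it. Ribosomal RNA, which also lacks a poly(A) tail, took 0.963 ± 0.101% of counts in Glut1Tg (SD, n = 4) and 0.610 ± 0.339% in WT (SD, n = 5; exact two-sided permutation p = 0.0794). It was 0.837, 1.054, 0.926 and 1.033% in Glut1Tg replicates 1 to 4 and 0.635, 0.482, 0.121, 1.023 and 0.789% in WT replicates 1 to 5, and WT replicate 4 was the highest WT library for both. Within Glut1Tg the histone sums and ribosomal RNA shares ran in opposite order.

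Apart from sex chromosomes, 22 genes had at most 4 counts in some libraries and at least 40 in all others. Of these, 9 were read in Glut1Tg replicate 3 alone, among them the C-type lectin genes Clec4n (237 counts) and Clec7a (256) and the neutrophil gene Camp (56). Another 4, including the ferritin light chain pseudogene Ftl2 (1500, 1427 and 2296 counts), were read in WT replicate 1 and Glut1Tg replicates 2 and 4 alone. The peptide transporter gene Slc15a2 had 1 count in Glut1Tg replicate 4 and 186 to 558 counts elsewhere, and Sh3rf3 had 321 counts in Glut1Tg replicate 2 and at most 2 elsewhere. Gbp6, called without a filter, was read in WT replicates 1 and 3 alone (73 and 97 counts).

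The oxidative phosphorylation list had a median log2 fold change of 0.3765 on the log2 CPM scale. Of 100 splits, 6 gave a median as large in size, the real one included, and the highest other was 0.7418, so chance cannot be excluded; that split compares Glut1Tg replicate 3 alone with the rest of mouse group 1, and among the 96 that do not compare 1 library in this way 5 were as large, the highest other being 0.5586. With each library's trend in GC content and transcript length removed the median was 0.3155 (camera adjusted p = 1.7e-15), which argues against that trend as the whole cause. Among males alone it was 0.5833. The female Glut1Tg libraries, replicates 2 and 4, had list means 0.09 above the WT mean and so did not carry the difference. The male Glut1Tg libraries are those with the highest list means, so choosing males was bound to raise the median. Sex within Glut1Tg thus cannot be told apart from whatever else set those libraries apart. An effect of the transgene in some cultures and not in others may remain and was not tested, and the libraries with the highest list means also stood apart otherwise, replicate 3 by mast cell and myeloid means of 3.80 and 2.89 above WT and replicate 1 by a cell cycle mean of 1.54.

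In Glut1Tg replicate 3, 88% (22 of 25) of the measured mast cell, basophil and myeloid list members had their highest value, a share that restates why this library was looked at and tests nothing. Of the 9 mast cell and 16 myeloid members, 6 and 2 had at least 10 CPM in the WT mean and 0 and 1 belong to another list. The ratio of the summed CPM of 14 myeloid members to Cpa3 was 0.269. It lay within the 0.0889 to 6.13 of the other libraries, the comparison written first. That range reaches up through libraries with little Cpa3, in which other myeloid transcripts weigh more. Without WT replicate 2 and Glut1Tg replicate 1, which had the least Cpa3, the range was 0.0889 to 0.283 and still held 0.269. More of the same mast cells would not raise the ratio above the 0.0889 of WT replicate 4. The sum of 449.6 lay above the 148.5 which that ratio allows at 1670 CPM of Cpa3, which argues against this explanation. The sum also lay above the 87.2 to 130.4 (95% prediction interval) of a line through the other 8 libraries. That line was fitted up to 524.2 CPM of Cpa3, so its interval at 1670 CPM rests on the line staying straight well beyond its range. Cells of another type or mast cells in another state may be present and stay open, with no sort named in the labels. Replicate 3 was picked for its high values, so its own mast cell mean tests nothing about the transgene. Glut1Tg replicates 1, 2 and 4 had mast cell means of -0.26, 4.9 and 3.64 log2 CPM, within the -0.715 to 4.94 of WT. These libraries thus carried the transgene without a mast cell mean above WT.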
